A study of Mus musculus with 15 samples.

How the data were processed

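RNA was measured by paired-end sequencing (150 bp reads) in 15 mouse tumours, 4 without treatment beyond vehicle, 4 treated with dasatinib, 3 with the antibody combination and 4 with both. Read pairs were counted per gene by the authors with featureCounts 1.6.0 over exons, in reverse-stranded mode (strand setting 2) and with the GENCODE M36 annotation, per the file headers. Alignment with STAR 2.7.9a to GRCm39 and quality control with FastQC 0.11.8 are named in the submitters' processing notes. The deposited values are raw counts for 78239 genes in each library, 1 library per table, with no normalization recorded. The counting command names no option for reads that map to several places, so genes with near-identical copies are uncertain. Coordinates are those of the deposited tables on GRCm39.

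Gene symbols and gene classes were taken from GENCODE M21, an annotation of the earlier build GRCm38, by the stable part of the gene identifier. Of the deposited identifiers, 51498 (65.8%) matched, and they held at least 97.2% of the counts of each library. Another 58 identifiers shared a symbol with another gene. Genes without a match kept their identifier and stayed in all tests.

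Groups were read from the sample titles and treatment labels. The titles of the untreated group hold a bare C, which was taken as vehicle control. The labels do not say whether each tumour came from its own mouse, so p-values measure the spread between these tumours. Replicate numbers were taken to pair control with ITC, where tumours of the same number deviated together in all 3 pairs (r from 0.276 to 0.396 of their deviations from the group means), as they would in 2 of 24 ways of pairing them. This is a hint from the data, since the labels name no pairs and only 2 of the other 18 pairs of the same number had r over 0.1. No library was a copy of another: the smallest difference between a pair within a group was 7.61 times that of counting noise (chi-square per degree of freedom).

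Total counts ran from 11812589 to 17250348 per library. Genes were kept if they passed edgeR's filterByExpr by group (minimum count 10), which left 17371. Libraries were scaled with TMM, with factors from 0.939 to 1.05. A quasi-likelihood model with 1 mean per group and no covariate was fitted to all 15 libraries with edgeR 4.0.16 in R 4.3.3 (robust estimation, 11 residual degrees of freedom). The biological coefficient of variation was 0.226. Contrasts gave 6 comparisons: each treatment against control, the combination against each single treatment, and the interaction, defined as the combination minus ITC minus the difference of dasatinib and control. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Principal components were taken from log2 CPM (prior count 2) of the 1000 most variable genes.

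Gene lists of cell types and pathways, 45 in all, were written from general knowledge before the data were examined. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the 41 lists that had at least 3 measured genes. Camera with a correlation estimated per list and fry, a test of each list on its own, were run beside it. The lists of NK cell, B cell, neutrophil and Y chromosome genes had too few measured genes and were not tested. The level of a list in a library is the mean log2 CPM of its measured genes. Adjustment over the list alone means Benjamini-Hochberg over the measured genes of that list. Several lists share genes, and tumour cells also express some of the genes.

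The tests, thresholds, lists, alternatives and the rule for naming genes were set before the data were examined. Named genes are the 8 called genes with the largest fold change in each direction in each comparison or, since none passed, the 3 with the smallest p in each direction. To these come up to 4 genes per called list with the smallest p in the direction of the list, and 10 genes named in any case (Rb1, Trp53, Pdcd1, Ctla4, Cd274, Cd8a, Foxp3, Csf1r, Kit and Ascl1).

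The procedure was tested on simulated counts drawn from the means and library sizes of the real data, with 200 of 17371 genes changed. Each gene was drawn independently, with no tumour that stood apart and no trend with gene length. The shares below therefore do not give the power in the real data. For dasatinib against control, 65% of genes changed 2-fold and 86% of those changed 4-fold were recovered, with 3.21% false calls. For ITC against control these were 53%, 78% and 1.50%, for the combination against control 55%, 86% and 6.00%, for the combination against dasatinib 57%, 84% and 4.73%, and for the combination against ITC 56%, 74% and 4.41%.

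Alternatives planned in advance were DESeq2 1.42.0 size factors and its Wald test, limma voom with sample quality weights, no filter and a stricter filter, other thresholds, a fit on the compared groups alone, the replicate number as a block, and leaving out each library in turn. Chosen after the data were seen were covariates for skeletal muscle and adipocyte levels, a covariate for the slope of expression on gene length, list counts with no filter, a replicate block on control and ITC replicates 1 to 3 alone, and simulated counts of shared genes. That slope was fitted per library over 10722 genes with a mean log2 CPM above 3. Comparisons were also repeated on other divisions of the same libraries, 35 for each pair of groups and 100 random ones for the interaction. Correlations across libraries were tested with 100000 permutations and single scores with exact permutations. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Bias from GC content was not tested, because no sequence of the build used was at hand.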

Results

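RNA was measured in 15 subcutaneous tumours grown from RP cells, a mouse small cell lung cancer line that lacks Rb1 and Trp53, in the flanks of female F1 mice (C57BL/6J crossed with 129S1/Sv) 8 weeks old. Treatment began at a tumour volume of about 50 mm3. The 4 groups were control (n = 4), dasatinib at 30 mg/kg daily (n = 4), antibodies against PD-1 and CTLA4 at 100 µg of each per mouse, a combination named ITC in the labels (n = 3), and dasatinib together with ITC (n = 4). Dasatinib inhibits the ABL and SRC family kinases, KIT and PDGF receptors. The control titles carry a bare letter C, which was read as the vehicle arm. The total gene count per library was 12059580 to 16527511 in control, 12195920 to 16332440 with dasatinib, 11812589 to 17250348 with ITC and 14228238 to 16421474 with both. The deepest library had 1.46 times the counts of the shallowest. Levels are given as CPM (gene counts scaled to library size, mean ± SD over the libraries of a group), and fold changes as log2 values ± the standard error of the fit.

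The genes deleted in the injected cells were examined first. Rb1 (ENSMUSG00000022105.7, chromosome 14, 73421113 to 73563262 in GRCm39) had 157 to 237 CPM in the 15 libraries, with group means of 196 ± 28.3 in control, 188 ± 21.6 with dasatinib, 191 ± 18.3 with ITC and 208 ± 9.24 with both. Trp53 (ENSMUSG00000059552.14, chromosome 11, 69471185 to 69482699) had 13.5 to 24.5 CPM, with group means of 16.8 ± 2.65, 16.9 ± 1.46, 19.3 ± 4.52 and 17.4 ± 2.34 in the same order. Counts summed over a whole gene cannot show the loss of single exons, so these values do not check the knockout. Ascl1, the transcription factor of neuroendocrine small cell lung cancer, had 926 ± 96.7 CPM in control, 883 ± 31.8 with dasatinib, 817 ± 41.2 with ITC and 916 ± 64.6 with both.

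Some libraries stood apart from the others of their treatment group. The first principal component held 48.6% of the variance of the 1000 most variable genes and separated ITC replicate 2, at 76.8, from the other libraries, at -35.4 to 23.9. Control replicate 4 had the highest adipocyte level, with Fabp4, a fatty acid carrier of fat cells, at 530 CPM against a mean of 31.8 in the other controls. The skeletal muscle list ranged from -1.78 to 6.11 in mean log2 CPM over the 15 libraries and differed by less between the groups than within them. The libraries also differed in how expression depended on gene length: the slope of log2 expression on log2 exon length ran from -0.21 in control replicate 2 and -0.19 in dasatinib replicate 3 to 0.14 in ITC replicate 1.

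**Figure D1:**
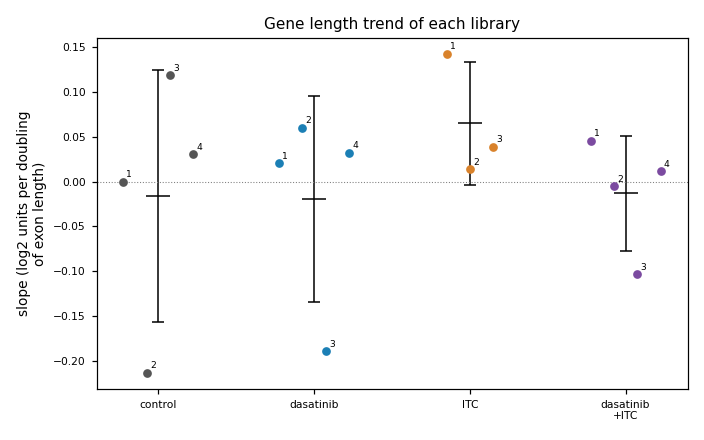
Slope of log2 expression on log2 exon length (log2 units per doubling of length, vertical axis) of each library by treatment group, numbered by replicate. Black bars are group means and whiskers 1 SD. Control replicate 2 and dasatinib replicate 3 lie lowest, at -0.21 and -0.19.

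The comparison of dasatinib with control asks what the kinase inhibitor did to tumours in the absence of antibodies. Dasatinib tumours had lower levels of plasma cell and macrophage genes. All 10 measured plasma cell genes were lower, with a median log2 fold change of -3.01, including the immunoglobulin genes Igha (-4.71 ± 1.46) and Igkc (-3.99 ± 1.34). Igkc had 13.6 ± 9.05 CPM in control (n = 4) and 0.853 ± 0.609 CPM with dasatinib (n = 4). Of the 10 measured genes of alternatively activated macrophages, 9 were lower, with a median of -1.84. Among these were Cd163, the haemoglobin scavenger receptor (-2.83 ± 0.73), and the C-type lectins Clec10a (-2.04 ± 0.58) and Mgl2 (-1.08 ± 0.36). The plasma cell list had an adjusted p of 4.93e-13 and the alternatively activated macrophage list 1.92e-10 by camera with a preset correlation, but 0.254 and 0.267 with an estimated correlation. Adjusted over the list alone, 3 and 5 genes of these lists passed. Without control replicate 4, the alternatively activated list had a median of -0.71, and Cd163 stood at -1.52 ± 0.54 and Mgl2 at -0.57 ± 0.30.

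Stromal and macrophage genes were also lower. Median log2 fold changes were -1.21 for the fibroblast list, lower in 14 of 14 genes, -0.62 for the endothelial list, lower in 16 of 16, -0.92 for the macrophage list, lower in 15 of 15, and -1.07 for the complement list, lower in 12 of 12. Their adjusted p was 0.358 with an estimated correlation. Without control replicate 4 these medians were -0.10, -0.18, -0.49 and -0.53, and camera did not call the fibroblast (adjusted p = 0.196) and endothelial lists (0.129). Examples were Pi16, a marker of adventitial fibroblasts (-1.80 ± 0.57), Dcn, the matrix proteoglycan decorin (-2.38 ± 0.98), and Pecam1, an endothelial adhesion molecule (-0.95 ± 0.42). Control replicate 4 had 95.3 CPM of Dcn against a mean of 7.65 CPM in the other controls, and without it Dcn stood at -0.43 ± 0.65, Pi16 at -0.91 ± 0.46 and Pecam1 at -0.53 ± 0.39. In the opposite direction, 7 of 10 mast cell genes were higher, with a median of 0.29 and an adjusted p of 0.358 with an estimated correlation. All 12 measured genes of the mitochondrial genome were also higher, with a median of 0.27 and an adjusted p of 0.395 with an estimated correlation. Camera did not call the mast cell list without control replicate 1 (adjusted p = 0.0872) or 2 (0.128), and its median was 1.10 without control replicate 4 and 0.08 without dasatinib replicate 4. The mitochondrial list was not called without control replicate 3 (adjusted p = 0.429) or dasatinib replicate 4 (0.183), and its median was 0.48 without control replicate 1 and 0.47 without dasatinib replicate 2.

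Mcpt2, which encodes a mast cell protease (ENSMUSG00000022226.7, chromosome 14, 56279498 to 56282099), had the smallest p of any gene in this comparison. It had 2.13 ± 0.822 CPM in control and 6.92 ± 2.00 CPM with dasatinib, a log2 fold change of 1.70 ± 0.34, and each of the 4 dasatinib tumours lay above each of the 4 controls. Its counts come from a family of similar proteases and are therefore uncertain. Next came Ifi213, an interferon-inducible gene (0.60 ± 0.15), and Pet2 (0.34 ± 0.09), and among the lower genes Pth1r, the parathyroid hormone receptor (-3.01 ± 0.78), and Fcna, a ficolin of macrophages (-2.67 ± 0.69), at -1.46 ± 0.53 and -1.63 ± 0.58 without control replicate 4. None of the 17371 genes passed an adjusted p of 0.05 in edgeR, where the lowest was 0.9999, and 463 had an unadjusted p under 0.05 against 868.55 by chance. DESeq2 called 1 gene, Mcpt2 (adjusted p = 0.0235), and limma voom called 0. Camera called 29 of 41 lists, 3 higher and 26 lower, against 0 with an estimated correlation and 0 by fry, and 17 without control replicate 4.

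**Figure D2:**
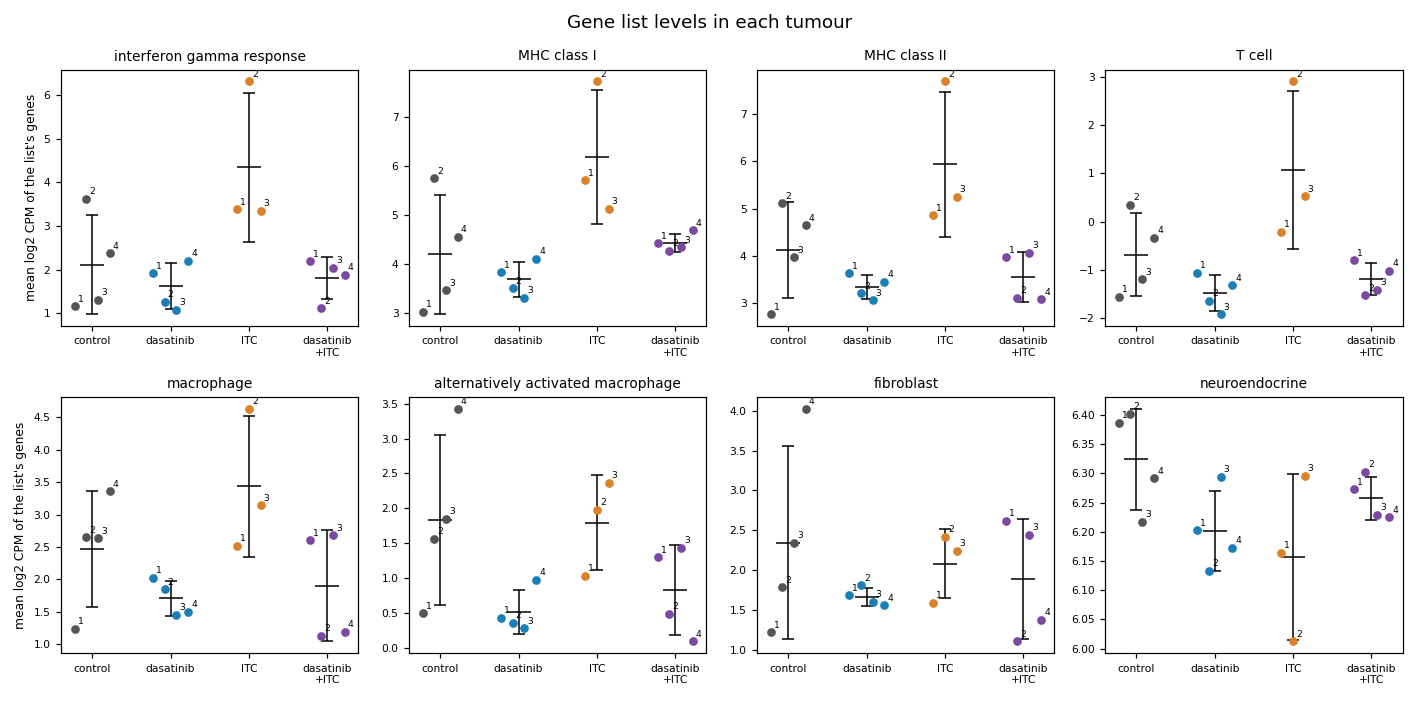
Mean log2 CPM of the measured genes of 8 lists (vertical axes) in each tumour by treatment group, numbered by replicate. Black bars are group means and whiskers 1 SD. ITC replicate 2 lies highest in the interferon gamma list, at 6.31, and control replicate 2, at 3.62, lies above the other ITC tumours.

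The comparison of ITC with control asks what the checkpoint antibodies did on their own. ITC tumours had higher levels of interferon gamma, antigen presentation and T cell genes. All 19 measured interferon gamma response genes were higher, with a median log2 fold change of 2.76, as were 16 of 16 MHC class I genes (2.06), 8 of 8 MHC class II genes (2.16), 9 of 9 T cell genes (2.59) and 6 of 6 cytotoxic lymphocyte genes (2.81). Of the 16 genes in each of the T cell and cytotoxic lists, only 9 and 6 passed the count filter. Enough counts in 3 libraries sufficed for it, so a gene could pass through the ITC tumours alone. This limits what the counts of genes in 1 direction show in each comparison with ITC, here and below. Adjusted over the list alone, 19, 15, 8, 7 and 6 genes of these lists passed, whereas 0 did when adjusted over all genes tested. The interferon gamma level was 4.34 ± 1.70 in mean log2 CPM with ITC (3.38, 6.31 and 3.35 in replicates 1 to 3) and 2.12 ± 1.14 in control, where replicate 2, at 3.62, lay above ITC replicates 1 and 3. Camera gave this list an adjusted p of 2.33e-23, but the adjusted p was 0.196 for each of the 5 lists with an estimated correlation. With ITC replicate 2 left out, the 5 medians were 0.86, 0.76, 0.60, 0.88 and 0.87, and camera still called each list, at an adjusted p of 4.04e-11 for the interferon gamma list and 0.00437 for the cytotoxic list. Between tumours of the same replicate number, the interferon gamma level was higher with ITC by 2.21, 2.69 and 2.03 in replicates 1 to 3.

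Ciita, the master regulator of MHC class II (ENSMUSG00000022504.11, chromosome 16, 10297923 to 10346282), had 5.75 ± 2.58 CPM in control (n = 4) and 28.7 ± 25.6 CPM with ITC (n = 3), a log2 fold change of 2.31 ± 0.47, and each ITC tumour lay above each control. Cd274, which encodes PD-L1 (chromosome 19, 29344855 to 29365495), had 2.80 ± 1.31 and 15.4 ± 17.2 CPM (2.44 ± 0.59), and Cd8a, the coreceptor of cytotoxic T cells, 0.393 ± 0.528 and 4.50 ± 6.06 CPM (3.44 ± 1.03). In ITC replicate 2, Cd274 had 35.3 CPM against 5.47 and 5.40 in replicates 1 and 3, and Cd8a 11.5 against 0.911 and 1.09, with 1.15 in control replicate 2. Without ITC replicate 2, Ciita stood at 1.27 ± 0.33, Cd274 at 0.95 ± 0.40 and Cd8a at 1.30 ± 0.90. Further examples were the guanylate-binding protein gene Gbp5 (2.80 ± 0.78), the peptidase gene Erap1 (1.06 ± 0.25), the MHC class II gene H2-Eb1 (2.35 ± 0.74), the T cell receptor gene Trbc2 (2.81 ± 0.77) and the granzyme gene Gzmb (3.50 ± 1.10), which stood at 0.89 ± 0.60, 0.49 ± 0.15, 0.80 ± 0.59, 1.14 ± 0.65 and 1.08 ± 0.97 without ITC replicate 2. H2 class I and T cell receptor constant genes are near-identical families whose counts can be shared between members.

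Macrophage genes of the classically activated kind were higher in 7 of 7 cases (median 1.49, adjusted p = 0.196 with an estimated correlation), with Il1b at 2.99 ± 0.70 and Nos2, the inducible nitric oxide synthase, at 1.38 ± 0.38. Also higher were the macrophage list (1.32, in 14 of 15 genes, adjusted p = 0.346 with an estimated correlation), the checkpoint list (1.25, 6 of 7, 0.196), the type I interferon list (0.97, 20 of 20, 0.303) and the chemokine list (0.91, 12 of 15, 0.287). Lower were the adipocyte list (-3.88, in 9 of 9 genes, adjusted p = 0.552 with an estimated correlation), the fibroblast list (-1.02, 13 of 14, 0.632) and the neuroendocrine list (-0.13, 16 of 20, 0.303), where Dll3, a Notch ligand of these tumours, stood at -0.57 ± 0.20. Pdcd1, the gene of the antibody target PD-1, had a log2 fold change of 2.76 ± 1.17, but 0.72 ± 1.19 without ITC replicate 2 and 4.82 ± 1.43 without control replicate 2. Il1b and Dll3 stood at 1.19 ± 0.49 and -0.37 ± 0.19 without ITC replicate 2. Ctla4, with 0 to 21 counts, and Foxp3, the regulatory T cell factor, with 0 to 12 counts, reached the minimum count in too few libraries to be tested. Without ITC replicate 2, the classically activated list had a median of 0.99 (adjusted p = 0.00150 by camera), and camera did not call the macrophage (median 0.22, adjusted p = 0.0958), checkpoint (0.44, 0.0537), type I interferon (0.05, 0.0591), chemokine (0.27, 0.0537), adipocyte (-3.48, 0.0537) and neuroendocrine lists (-0.07, 0.600). Without control replicate 4 the adipocyte median was -0.40 (adjusted p = 0.986) and the fibroblast median 0.36 (0.273), with the replicate block 0.05 and 0.41, and the fibroblast list was not called without control replicate 3 (0.135) or ITC replicate 1 (0.245). The neuroendocrine list was not called without control replicate 1 (adjusted p = 0.0517) and had a median of -0.08 without control replicate 2, and the chemokine list a median of 0.58 without control replicate 1.

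The 3 genes with the smallest p in each direction were Ciita, Cyld, a deubiquitinase of NF-kB signalling (0.45 ± 0.10), and Tlr12 (3.12 ± 0.68) among the higher, and Dapk2 (-0.54 ± 0.12), Metrn (-0.91 ± 0.21) and Fgfrl1 (-0.59 ± 0.14) among the lower, with Ciita at 1.27 ± 0.33 and Tlr12 at 1.75 ± 0.58 without ITC replicate 2. EdgeR called 0 genes (lowest adjusted p = 0.508), and 1241 had an unadjusted p under 0.05, 836 higher and 405 lower. With the replicate number as a block, on control and ITC replicates 1 to 3, edgeR called 126 genes, all higher with ITC, among them H2-Eb1 (2.28 ± 0.19, adjusted p = 0.000309), Cd8a (3.56 ± 0.51, 0.00891), Cd274 (2.21 ± 0.32, 0.0105) and Ciita (2.09 ± 0.33, 0.0231), and 0 on these 6 libraries with no block. Camera then called 26 lists, and 0 with an estimated correlation (lowest adjusted p = 0.284) or by fry (0.202). Of the 21 lists called on all libraries, the block, which leaves out control replicate 4, ended the calls of the fibroblast (median 0.41, higher in 11 of 14), pericyte (0.09), endothelial (0.18), adipocyte (0.05), erythroid (-0.54) and immediate early lists (0.19), and 11 others were called, such as the monocyte list (0.64, 7 of 7) and the alternatively activated macrophage list (0.46, 9 of 10, adjusted p = 0.0163, and 0.352 with an estimated correlation). The complement list had a median of 1.39 with the block and 0.56 on all libraries, and the lists of dasatinib target kinases 0.27 against 0.13 and of SRC family and adhesion signalling 0.18 against 0.11. The labels do not say that the numbers mark pairs. The pairing was taken from how these same tumours deviated together, and the block removes that shared part from the error. Its adjusted p-values are therefore no independent test of ITC. The fit had 2 residual degrees of freedom, and another of the 24 ways of pairing gave 147 genes. Over all libraries DESeq2 called 3, Ciita (adjusted p = 0.00476), Cyld (0.0265) and Spn (0.0359), the last named here after its values were seen, and limma voom called 0. Camera called 21 of 41 lists, 15 higher and 6 lower, against 0 with an estimated correlation and 0 by fry.

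**Figure D3:**
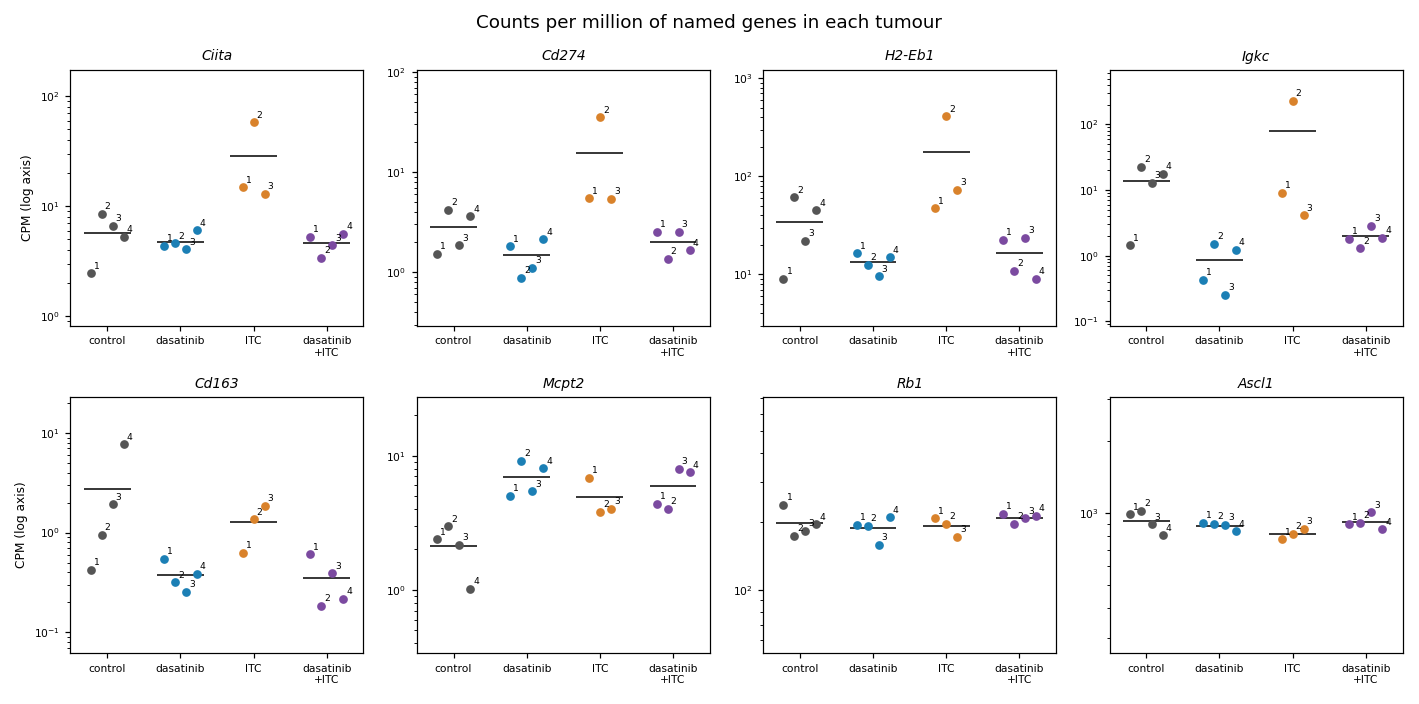
CPM of 8 named genes (vertical axes, logarithmic) in each tumour by treatment group, numbered by replicate, with black bars at the group means. Ciita reached 58.3 with ITC and at most 8.59 in control, and Mcpt2 from 1.01 to 2.98 in control and from 3.83 to 9.14 in the other 11 libraries.

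The comparison of the combination with control asks what both treatments did together. The interferon gamma list had a median log2 fold change of -0.76, lower in 19 of 19 genes, with an adjusted p of 0.0170 by camera and 0.639 with an estimated correlation, and Cd274 stood at -0.48 ± 0.57 and Csf1r, the receptor of macrophage growth factor, at -1.10 ± 0.69. Cd8a, at 0.148 ± 0.0996 CPM with both, had too few counts for a fold change against control. The genes of alternatively activated macrophages were lower, as with dasatinib alone (median -1.25, 9 of 10 genes, adjusted p = 0.394 with an estimated correlation), including Cd163 (-2.95 ± 0.73) and Mgl2 (-1.11 ± 0.36). Plasma cell genes had a median of -1.95 (9 of 10, 0.410). Without control replicate 2, the interferon gamma median was 0.03 (adjusted p = 0.380 by camera), and without replicate 2 of the combination -0.50 (0.345). Cd274 stood at -0.21 ± 0.63 without control replicate 2. Without control replicate 4, the alternatively activated list had a median of -0.44 (adjusted p = 0.00864 by camera) and Cd163 stood at -1.65 ± 0.54, Mgl2 at -0.60 ± 0.30 and Csf1r at -0.70 ± 0.73.

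Red cell and hypoxia genes were also lower. All 5 erythroid genes were lower, with a median of -1.37, 3 passed when adjusted over the list alone, and the adjusted p was 0.394 with an estimated correlation. Hbb-bs, a beta globin gene, had 23.9 ± 18.7 CPM in control and 8.91 ± 2.29 CPM with both treatments (-1.43 ± 0.55), and Alas2, the haem synthesis enzyme of red cells, stood at -1.68 ± 0.47. All 16 hypoxia and glycolysis genes were lower by a small amount (median -0.32, adjusted p = 0.394 with an estimated correlation), such as Hk2, a hexokinase (-0.52 ± 0.20), and Adm, adrenomedullin (-0.81 ± 0.33). Genes of the mitochondrial genome were higher in 12 of 12 cases (median 0.48, adjusted p = 0.394 with an estimated correlation), and so were 6 of 10 mast cell genes (median 0.38, adjusted p = 0.410 with an estimated correlation), led by the tryptase gene Tpsab1 (1.62 ± 0.39), which passed when adjusted over the list alone. All 4 lists were called by camera with each library left out, but without control replicate 4 the erythroid median was -0.74, Hbb-bs stood at -0.74 ± 0.46 and Hk2 at -0.27 ± 0.17, the mitochondrial median was 0.28 without control replicate 3, and the mast cell median 0.06, 0.12, 0.15 and 1.37 without control replicates 1 to 4, and 0.65 and 0.25 without replicates 2 and 3 of the combination.

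The genes with the smallest p were Ifi213 (0.72 ± 0.15), Pet2 (0.44 ± 0.09) and Mcpt2 (1.49 ± 0.34), the same 3 genes as with dasatinib alone, against the same controls, and, among the lower, Fcna (-3.58 ± 0.74), Cd163 and Phf24 (-2.40 ± 0.65). In edgeR, 0 genes passed (lowest adjusted p = 0.999), and 482 had an unadjusted p under 0.05. DESeq2 called 1, Pet2 (adjusted p = 0.0423), and limma voom called 0. Camera called 26 of 41 lists, 2 higher and 24 lower, against 0 with an estimated correlation and 0 by fry. It called 15 without control replicate 4 and 12 without replicate 2 of the combination.

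The comparison of the combination with dasatinib asks what the antibodies added in the presence of dasatinib. Of the MHC class I genes, 15 of 16 were higher (median log2 fold change 0.74, adjusted p = 2.68e-06 by camera and 0.744 with an estimated correlation). The level of the list was 4.27 to 4.68 in the 4 combination tumours and 3.30 to 4.10 in the 4 dasatinib tumours. Examples were the proteasome gene Psmb8 (1.41 ± 0.92) and the transactivator Nlrc5 (1.29 ± 0.84), and 0 genes of the list passed when adjusted over the list alone. Interferon gamma genes had a median of 0.12, higher in 12 of 19, and camera did not call them at an adjusted p = 0.375. Cd274 differed by less than its standard error (0.43 ± 0.59), and Cd8a, at 0.192 ± 0.182 and 0.148 ± 0.0996 CPM, had too few counts in both groups for a fold change. Macrophage genes (median 0.33, 14 of 15, adjusted p = 0.912 with an estimated correlation) and plasma cell genes (1.19, 9 of 10, 0.744) were higher. The macrophage list was not called without dasatinib replicates 3 (adjusted p = 0.298) or 4 (0.173) or replicates 1 (0.858) or 3 (0.961) of the combination, and its median was 0.56 and 0.58 without replicates 2 and 4 of the combination.

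Hypoxia genes were lower in 16 of 16 cases (median -0.17, adjusted p = 0.744 with an estimated correlation), and erythroid genes in 5 of 5 (median -0.85, 0.744). Genes of the integrated stress response were lower in 12 of 15 (median -0.15, adjusted p = 0.566 with an estimated correlation), for example Chac1 (-0.34 ± 0.17), and cell cycle genes in 22 of 25 (median -0.06, 0.744). P53 target genes had the lowest adjusted p of the comparison with an estimated correlation, 0.482, but only 8 of 12 were lower (median -0.06). Without dasatinib replicate 1, the erythroid median was -0.48 (adjusted p = 0.336) and camera did not call the p53 target list (0.128), which was not called either without dasatinib replicate 3 (0.112) or replicate 1 of the combination (0.0624). Its median was -0.11 without dasatinib replicate 2, -0.10 without dasatinib replicate 4 and -0.10 without replicate 3 of the combination. The hypoxia list was not called without replicate 3 of the combination (median -0.08, adjusted p = 0.115) and had a median of -0.26 without replicate 4. The cell cycle list was not called without replicate 1 of the combination (0.0528), and its median was -0.11 without dasatinib replicate 4 or replicate 2 of the combination. The smallest p belonged to Pla2g2c (1.03 ± 0.30), Slc47a1 (0.77 ± 0.25) and Rsph1 (0.59 ± 0.20) among the higher genes, and to Pgam1-ps2 (-1.09 ± 0.38), Kcnk12 (-1.27 ± 0.45) and Rhod (-0.64 ± 0.23) among the lower. Pgam1-ps2 is a processed pseudogene, so its reads can belong to the parent gene. In edgeR, 0 genes passed (lowest adjusted p = 0.9999), 127 had an unadjusted p under 0.05, and DESeq2 and limma voom also called 0. Camera called 11 of 41 lists, 5 higher and 6 lower, against 0 with an estimated correlation and 0 by fry. It called 6 without replicate 1 of the combination, 6 with no filter on low counts, and 19 without replicate 2 or without replicate 4 of the combination.

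The comparison of the combination with ITC asks what dasatinib did in tumours that also received the antibodies. Immune genes were lower in the combination than with ITC, in a comparison that shares its ITC libraries with that of ITC and control. Median log2 fold changes were -3.58 for the interferon gamma list, lower in 19 of 19 genes, -2.24 for MHC class I, in 16 of 16, -2.92 for MHC class II, in 8 of 8, -3.87 for T cell genes, in 9 of 9, and -4.24 for cytotoxic lymphocyte genes, in 6 of 6. Adjusted over the list alone, 19, 16, 8, 8 and 6 genes passed. The interferon gamma list had an adjusted p of 1.08e-23 by camera, and all 5 lists had 0.140 with an estimated correlation. Cd274 had 15.4 ± 17.2 CPM with ITC (n = 3) and 2.02 ± 0.609 CPM with both (n = 4), a log2 fold change of -2.91 ± 0.60, and Cd8a stood at -4.85 ± 1.15, H2-Eb1 at -3.41 ± 0.78, Gbp5 at -4.09 ± 0.84 and Gzmb at -5.33 ± 1.28. Cd8a and Gzmb had few counts in the combination, so their fold changes are imprecise. Without ITC replicate 2, the 5 medians were -1.53, -1.03, -1.60, -2.16 and -2.47, all still called by camera (adjusted p = 1.08e-14 for the interferon gamma list), and Cd274 stood at -1.42 ± 0.40, Cd8a at -2.71, H2-Eb1 at -1.85 ± 0.58, Gbp5 at -2.18 ± 0.63 and Gzmb at -2.91 ± 1.11.

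Myeloid genes were lower as well. The macrophage list had a median of -1.82, lower in 15 of 15 genes, with Csf1r at -2.42 ± 0.74, and the classically activated list a median of -2.19, in 7 of 7, with Nos2 at -2.00 ± 0.39 and Il1b at -3.50 ± 0.72. Both had an adjusted p of 0.140 with an estimated correlation, and 11 of 15 and 5 of 7 genes passed when adjusted over the list alone. Of the 20 measured kinases that dasatinib inhibits, 19 had lower transcript levels (median -0.21, adjusted p = 0.140 with an estimated correlation). The 4 with the smallest p were Lck (-2.01 ± 0.51), Fgr (-2.28 ± 0.62), Hck (-3.24 ± 0.95) and Lyn (-2.39 ± 0.73), kinases of T cells and myeloid cells, while Kit, which was expressed in all groups, stood at -0.24 ± 0.13. Plasma cell genes had a median of -4.48 (8 of 10 lower, adjusted p = 0.247 with an estimated correlation), and Igkc had 229 CPM in ITC replicate 2 against 9.17 and 4.10 CPM in replicates 1 and 3. Mitochondrial genes were higher in 12 of 12 cases (median 0.67, adjusted p = 0.140 with an estimated correlation). The macrophage median without ITC replicate 2 was -0.81 and still called by camera (adjusted p = 0.000113), the plasma cell median was -0.70 and not called (0.0876), and the mitochondrial median was 1.07, against 0.40 without ITC replicate 3. In the same fit without ITC replicate 2, Csf1r stood at -1.20 ± 0.65, Il1b at -1.70 ± 0.50, Lck at -0.77 ± 0.38, Fgr at -0.56 ± 0.40, Hck at -0.97 ± 0.72, Lyn at -0.46 ± 0.45 and Igkc at -1.77 ± 0.75.

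This comparison had the most genes at an unadjusted p under 0.05 of the 6 that were made, 1774, with 1224 lower and 550 higher. The smallest p belonged to Akna (-1.60 ± 0.27), Etv5, a transcription factor downstream of FGF and ERK signalling (-1.08 ± 0.19), and Ciita (-2.62 ± 0.47, and -1.58 ± 0.33 without ITC replicate 2) among the lower, and to Hpgd, a prostaglandin-degrading enzyme (0.98 ± 0.21), Fli1 (0.41 ± 0.10) and Id4 (0.67 ± 0.17) among the higher. At an adjusted p of 0.05, edgeR called 0 genes (lowest 0.167), but DESeq2 called 203 and limma voom 3, and edgeR called 95 without ITC replicate 1 and 1 without ITC replicate 2. With no filter on low counts edgeR called 58. Camera called 25 of 41 lists, 2 higher and 23 lower, against 0 with an estimated correlation and 0 by fry.

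The interaction asks whether dasatinib acted differently in the presence of the antibodies, as the change from ITC to the combination minus the change from control to dasatinib. The interferon gamma list had a median of -2.34, with all 19 genes below 0, and MHC class II (-1.87, 8 of 8), MHC class I (-1.12, 16 of 16), T cell genes (-1.79, 9 of 9) and cytotoxic lymphocyte genes (-3.12, 6 of 6) pointed the same way. Adjusted p by camera was 1.68e-18 for the interferon gamma list, but 0.393 with an estimated correlation for that list, both MHC lists and the cytotoxic list, and 0.50 for the T cell list. Fibroblast genes (median 1.34, 14 of 14 above 0) and adipocyte genes (3.73, 9 of 9) lay on the other side, with adjusted p of 0.571 and 0.605 with an estimated correlation. Without ITC replicate 2, camera still called the interferon gamma list (median -0.52, adjusted p = 3.73e-06) and MHC class II (-0.35, 0.0131), but not MHC class I (-0.21, 0.0753), T cell (-0.44, 0.50) or cytotoxic lymphocyte genes (-1.02, 0.0693). The MHC class I median was -2.16 without control replicate 2, and the cytotoxic median -2.08 without dasatinib replicate 1. Without control replicate 4 the fibroblast median was 0.14 (adjusted p = 0.817) and the adipocyte median 0.25 (0.743), the fibroblast list was also not called without replicate 1 of the combination (0.0845), and the adipocyte list not without ITC replicate 1 (0.0808) or 2 (0.127), dasatinib replicate 3 (0.142) or replicate 4 of the combination (0.151). The 3 genes with the smallest p in each direction were Ciita (-2.34 ± 0.65, and -1.32 ± 0.44 without ITC replicate 2), Fam129a (-0.93 ± 0.27) and Plekhb2 (-0.48 ± 0.14) below 0, and Fgfrl1 (0.68 ± 0.19), Dapk2 (0.61 ± 0.17) and Snrpert (0.67 ± 0.19), a processed pseudogene whose reads can belong to its parent, above 0. In edgeR, 0 genes passed (lowest adjusted p = 0.999), 473 had an unadjusted p under 0.05, and DESeq2 and limma voom also called 0. Camera called 24 of 41 lists, 7 above and 17 below 0, against 0 with an estimated correlation and 0 by fry, and 12 without ITC replicate 2.

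The fold changes of dasatinib and of the combination were set side by side, both against the same 4 controls. Across 17371 genes, which are not independent replicates, Pearson's r was 0.677 and 72.5% of genes had the same sign. Simulated libraries with no change, with the controls redrawn as well, gave a mean r of 0.502 in 100 simulations, at most 0.536. Each gene was drawn independently around its control mean, with 1 dispersion for all groups. Between real controls the chi-square per degree of freedom was 24.7 to 76.9, against 8.09 to 33.5 with dasatinib and 7.61 to 23.9 with both. A wider spread of the shared controls would itself raise r, so 0.536 is no upper limit for chance. The observed covariance was 0.0505 and the simulated one 0.0510, a difference of -0.000504. With 2 controls given to each comparison, so that they shared no library, the mean r over 6 such divisions was -0.0635, from -0.250 to 0.139. At an unadjusted p under 0.05, 45 genes were higher in both comparisons, among them Mcpt2, Ifi213 and Pet2, and 103 were lower in both, against 1.69 and 5.08 for independent lists. Libraries simulated in the same way gave on average 99.95 higher (83 to 128) and 68.4 lower (55 to 84) in 20 simulations, because of the shared controls. These simulations had more genes in each comparison (806.9 and 815.85 on average). With the controls divided, 8.33 and 5.83 were shared on average, at most 10 and 11. No gene passed the adjusted threshold in both with edgeR.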

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

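The tests in this part were chosen after the results were seen, except the sum of Mcpt1 and Mcpt2 and the correlation of Mcpt2 with Cpa3, which were set before. In some groups 1 tumour stood apart, with a gap to the nearest other tumour, as a share of the range of the group, above Dixon's limit for 4 values, and control replicate 4 did so in 5 values. For Fabp4 this share was 0.940 (530 CPM against a mean of 31.8 in the other controls), for Dcn 0.917, for Pth1r 0.891 (7.15 against 0.815 CPM), for the mast cell list 0.845 and for Slc47a1 0.841. Control replicate 2 stood apart in Psmb8 (0.880, 80.2 against 7.94 CPM), Metrn (0.990) and Tlr12 (0.899), and control replicate 1 in the plasma cell list (0.863), where it was lowest. Dasatinib replicate 1 was highest in Pdcd1 (1, with 0 counts in the other 3), Alas2 (0.872), Gzmb (0.867), Tlr12 (0.858) and Clec10a (0.843). Replicate 3 stood apart in the SRC family and adhesion list (0.920, lowest) and Ifi213 (0.843, highest), and replicate 4 in Chac1 (0.839, lowest). In the combination, replicate 1 stood apart in Tlr12 (0.882) and Pgam1-ps2 (0.852), and replicate 2 in Cd8a (0.844, with 0 counts). These were 20 of 321 groups of values tested, where chance gives about 1 in 20, or 16.05, for independent values with a normal spread. Several of these genes had few counts and many values are related, so 16.05 is only a rough guide. The limit is for 4 values, so the ITC group (n = 3), with its replicate 2, was not tested.

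The effect of dasatinib differed between tumours with and without the antibodies in 24 lists, by the test of the interaction with camera, and in 0 with an estimated correlation, where the lowest adjusted p was 0.393. Below 0 were the lists of cytotoxic lymphocytes (median -3.12), interferon gamma response (-2.34), MHC class II (-1.87), T cells (-1.79), classically activated macrophages (-1.65), checkpoints (-1.22), MHC class I (-1.12), macrophages (-1.0), type I interferon response (-0.85), chemokines (-0.60) and complement (-0.57). Smaller differences below 0 were found for the STING pathway (-0.32), hypoxia and glycolysis (-0.30), immediate early genes (-0.29), integrated stress response (-0.18), dasatinib target kinases (-0.18) and SRC family and adhesion signalling (-0.17). Above 0 were adipocyte (3.73), fibroblast (1.34), extracellular matrix (0.47), pericyte and smooth muscle (0.44), endothelial (0.37), mitochondrial (0.37) and neuroendocrine genes (0.14).

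Many of these differences hung on single libraries. Without ITC replicate 2, camera did not call the lists of cytotoxic lymphocytes (median -1.02), T cells (-0.44), checkpoints (-0.41), MHC class I (-0.21), macrophages (0.17), type I interferon response (0.05), chemokines (-0.11), complement (0.15), the STING pathway (-0.10), dasatinib target kinases (-0.12), adipocyte (3.30), extracellular matrix (0.46), pericyte (0.43) and neuroendocrine genes (0.10), and it still called interferon gamma response (-0.52), MHC class II (-0.35), classically activated macrophages (-0.55), hypoxia (-0.61), integrated stress (-0.33), endothelial (0.68) and mitochondrial genes (0.80). Without control replicate 4 it did not call fibroblast (0.14), adipocyte (0.25), extracellular matrix (0.13), pericyte (0.07) and endothelial genes (0.05), and complement stood at -1.22. Without control replicate 3 it lost checkpoints (-1.39), complement (-0.51), integrated stress (-0.09), extracellular matrix (0.21), pericyte (0.52) and endothelial genes (0.26), and without control replicate 1 macrophages (-0.71), complement (-0.25), SRC family and adhesion signalling (-0.14) and mitochondrial genes (0.22), with extracellular matrix at 0.77, endothelial genes at 0.61 and the STING pathway at -0.20. MHC class I stood at -2.16 and integrated stress at -0.29 without control replicate 2.

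Of the other ITC libraries, leaving out replicate 1 ended the calls of hypoxia (-0.13), adipocyte (3.22) and endothelial genes (0.22), with integrated stress at -0.11, and leaving out ITC replicate 3 those of hypoxia (-0.20), integrated stress (-0.14), endothelial (0.28) and mitochondrial genes (0.11), with the STING pathway at -0.51 and immediate early genes at -0.46. Lost without dasatinib replicate 1 were checkpoints (-0.88), with cytotoxic lymphocytes at -2.08 and immediate early genes at -0.15, without dasatinib replicate 2 mitochondrial genes (0.16), with target kinases at -0.11, and without dasatinib replicate 3 pericyte (0.40), endothelial (0.32), adipocyte (3.41) and extracellular matrix genes (0.45), with integrated stress at -0.10. Without dasatinib replicate 4 mitochondrial genes stood at 0.56. In the combination, leaving out replicate 1 ended the calls of fibroblast (1.24), pericyte (0.25), endothelial (0.27) and extracellular matrix genes (0.24), replicate 2 those of macrophages (-0.76), chemokines (-0.61) and complement (-0.48), with the STING pathway at -0.18, replicate 3 that of extracellular matrix (0.36) and replicate 4 those of adipocyte genes (2.19) and complement (-0.43).

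Interferon gamma, antigen presentation and T cell genes were higher in the ITC tumours than in control or the combination. Against the combination, a larger share of host cells of every type in ITC is argued against by the T cell and endothelial levels. They exceeded those of the combination by 2.27 and 0.10, a difference of 2.17 (exact permutation p = 0.0286, the smallest that 3 against 4 can give). Both lists had been seen when this test was chosen, and T cell genes could pass the filter through the ITC tumours alone. ITC replicate 2 as the whole cause of the difference from the combination is argued against too: without it the interferon gamma list still had a median of -1.53 in the combination against ITC, and the lower of the other ITC tumours stood at 3.35 against at most 2.19 in the combination. Against control, ITC replicate 2 cannot be told apart from an effect of the antibodies where the tumours are taken as unpaired, since without it the median of that list was 0.86 and the other ITC tumours, from 3.35, did not exceed control replicate 2, at 3.62. Between tumours of the same replicate number the level was higher with ITC by at least 2.03 in replicates 1 and 3. The difference was 2.69 in replicate 2. These values cannot decide the question, because the pairing was taken from how the same tumours deviated together. The labels do not say that the numbers mark pairs. Lymphoid tissue in the samples cannot be told apart from infiltrating T cells, since B cell counts were 28.9% of T cell counts with ITC but 71.0% in control, 67.3% of them came from Pax5, a gene expressed in all libraries, and the excess over control was 15.5%. That the level in control makes this test void was decided after it was seen. An effect of the antibodies that dasatinib reduces stays open as a hypothesis, and so does chance for the number of lists.

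Stromal and macrophage genes were lower in both groups given dasatinib than in control. Fewer host cells of every type cannot be told apart from an effect of dasatinib: the mast cell level was higher by 0.50 and the endothelial level lower by 0.41, a difference of 0.92 (exact permutation p = 0.0286, the smallest that 4 against 4 can give), under the bound of 1 set for this test. The values of the stromal part go with surrounding tissue in control replicate 4, because without that library 0 of the 5 lists of fibroblast, endothelial, pericyte, adipocyte and matrix genes were still called lower with dasatinib (fibroblast adjusted p = 0.196, and 0.692 in both vs control). Fibroblast genes were also lower in ITC tumours, which had no dasatinib (median -1.02, in 13 of 14), but not without control replicate 4 (0.36) or with the replicate block on control and ITC replicates 1 to 3 (0.41). For the macrophage part this cannot be told apart, as 2 of 2 lists were still called but with medians of -0.49 and -0.71 in place of -0.92 and -1.84. Over all lists lower with dasatinib, 14 of 26 were still called, and 10 with covariates for muscle and fat. An effect of dasatinib on these cells stays open as a hypothesis.

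Mcpt2 was higher in both groups given dasatinib than in control. A mere shift of reads from Mcpt1, a gene chosen for this test, to Mcpt2 is argued against. The sum of both genes was higher by 1.54 with dasatinib (exact permutation p = 0.0286), with 1489 and 1099 counts in all. The sum cannot exclude that Mcpt1 itself was higher and that its reads were counted as Mcpt2. Low values in the 4 controls go with the data, since ITC tumours were also higher, by 1.21 ± 0.36 against 1.70 with dasatinib. More mast cells cannot be told apart, as Mcpt2 went weakly with Cpa3, a mast cell protease gene chosen for this test (r = 0.151, permutation p = 0.590, rho = 0.479, permutation p = 0.0734), with r = 0.772 without the 2 farthest libraries and -0.238 within groups. An effect of dasatinib on the gene stays open as a hypothesis.

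Each comparison was repeated on every division of its libraries into groups of the same sizes, 35 in number, or on 100 random ones for the interaction, the real one included. For genes called by edgeR, where the real count was 0, all 35 gave as many in each of the 5 comparisons of groups, and the highest count in another division was 399 for dasatinib vs control, 21 for ITC vs control, 71 for both vs control, 0 for both vs dasatinib and 0 for both vs ITC. For the interaction all 100 gave as many, and the highest was 124. Chance can be excluded only for 1 count taken alone, the 1774 genes at an unadjusted p under 0.05 in both vs ITC, which 1 division of 35 reached, the real one, with 1627 in the highest other. That is the smallest share possible, and with 18 counts examined it would not hold after correction. It cannot be excluded for such genes in dasatinib vs control (463, reached by 25, highest other 4418), ITC vs control (1241, 22, 3850), both vs control (482, 21, 2473), both vs dasatinib (127, 31, 819) or the interaction (473, 78, 4152).

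For lists called by camera chance cannot be excluded either, in dasatinib vs control (29 lists, reached by 2 divisions, highest other 30), ITC vs control (21, 16, 32), both vs control (26, 5, 31), both vs dasatinib (11, 11, 25), both vs ITC (25, 9, 26) and the interaction (24, 25, 33). Of the divisions of control and ITC, 8 part all 3 pairs of the same number, and of these 4 gave at least 1241 genes (highest other 2344) and 4 at least 21 lists (highest other 27). With the replicate number as a block the 126 genes stood against 0, 0 and 1 when the members of 1 pair were exchanged, and such divisions are too few for a share under 0.05. At an unadjusted p under 0.05 the block gave 1219 genes, against 78, 229 and 3005 with pair 1, 2 or 3 exchanged. Divisions that call up to 399 genes against 0 in the real one point to a structure of the samples that is not the treatment. That division is examined for gene length below.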

How the results depend on the processing

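The covariates for muscle and fat and for gene length, the list counts with no filter, and the block on 6 libraries were chosen after the data were seen, and the other alternatives before. In edgeR, 0 genes passed in each comparison (463, 1241, 482, 127, 1774 and 473 at an unadjusted p under 0.05 for dasatinib vs control, ITC vs control, both vs control, both vs dasatinib, both vs ITC and the interaction). DESeq2's Wald test called 1, 3, 1, 0, 203 and 0, limma voom called 3 in both vs ITC and 0 elsewhere, and no filter on low counts gave 1, 6, 0, 0, 58 and 0. Leaving out single libraries gave 0 to 95 genes in both vs ITC (95 without ITC replicate 1) and 0 in the others. DESeq2 size factors, the stricter filter, stricter thresholds, fits on 2 groups alone and both sets of covariates called 0 genes. Camera called 29, 21, 26, 11, 25 and 24 lists in the same order, but 0 in each comparison with an estimated correlation and 0 with fry. Muscle and fat covariates gave 12 lists in dasatinib vs control and 9 in both vs control, and no filter gave 6 in both vs dasatinib. Single libraries left out gave 17 to 30 lists in dasatinib vs control (17 without control replicate 4), 16 to 24 in ITC vs control, 12 to 31 in both vs control (12 without replicate 2 of both and 15 without control replicate 4), 6 to 19 in both vs dasatinib (6 without replicate 1 of both, 19 without replicate 2 or 4), 19 to 26 in both vs ITC and 12 to 27 in the interaction (12 without ITC replicate 2). The length covariate gave 29, 24, 23, 10, 26 and 24 lists. For named genes, 3051 values over 175 genes and comparisons included 46 changes of sign in results that did not pass, and 20 passed in DESeq2, 13 with a library left out, 6 with no filter and 2 in limma voom. The correlation of dasatinib vs control with both vs control went from 0.677 to -0.0635 with 2 controls for each.

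Replicate numbers are shared between groups, but over all groups libraries of the same number did not deviate together (r from -0.483 to 0.396 in 21 pairs, 5 over 0.1), and 2 of 15 libraries went best with their own number. With the number as a replicate block on all libraries, edgeR called 0 genes in each comparison and camera 29, 20, 24, 11, 24 and 22 lists. On control and ITC replicates 1 to 3 alone, with 2 residual degrees of freedom, the replicate block gave 126 genes and 26 lists in ITC vs control, and no block 0 genes. Another of the 24 ways of pairing these groups gave 147 genes.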

Other observations

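Of the tests in this part, the replicate block on 6 libraries, the one on the spread between tumours, the one on Xist and the one on exon lengths were chosen after the results were seen, while the refit with the length trend was set before its result was seen. Levels of macrophage genes are given by activation state. With ITC, the classically activated list stood at 2.23 ± 1.07 in mean log2 CPM (n = 3) against 0.75 ± 0.47 in control (n = 4), and the alternatively activated list at 1.79 ± 0.68 against 1.83 ± 1.21. Exact permutation p was 0.0286 for the first (0.488 adjusted over the lists) and 0.943 for the second, without regard to pairs. With the replicate number as a block on control and ITC replicates 1 to 3, both lists were higher with ITC, in 7 of 7 genes (median 1.30) and in 9 of 10 (median 0.46, adjusted p = 0.0163 by camera), but the adjusted p was 0.295 and 0.352 with an estimated correlation. With dasatinib (n = 4), both were low, at 0.24 ± 0.28 and 0.51 ± 0.31, and with both treatments (n = 4) at 0.28 ± 0.65 and 0.83 ± 0.64. The scavenger receptor Cd163 had 2.74 ± 3.35 CPM in control, 0.376 ± 0.125 with dasatinib, 1.28 ± 0.615 with ITC and 0.349 ± 0.193 with both. The inducible nitric oxide synthase Nos2 had 2.00 ± 0.677, 1.57 ± 0.815, 5.27 ± 2.23 and 1.31 ± 0.196 CPM in the same order.

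Lists of the tumour cell programme differed by small amounts between groups. Camera called the neuroendocrine list lower with ITC than in control (median -0.13, adjusted p = 0.00835). It also called the non-neuroendocrine list lower in the combination than with ITC (median -0.27, adjusted p = 0.00737). Neither of these was called with an estimated correlation or without ITC replicate 2. The neuroendocrine list stood at 6.32 ± 0.09 in mean log2 CPM in control, 6.20 ± 0.07 with dasatinib, 6.16 ± 0.14 with ITC and 6.26 ± 0.04 with both. Ascl1 differed from control by -0.07 ± 0.10 with dasatinib and by -0.18 ± 0.10 with ITC, and Dll3 had 21.1 ± 2.83 CPM in control and 14.1 ± 3.93 with ITC. The cell cycle list ranged from 7.51 to 7.75 in control, 7.62 to 7.75 with dasatinib, 7.57 to 7.64 with ITC and 7.59 to 7.70 with both.

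On average over 10 of the immune lists, tumours treated with dasatinib, alone or with ITC, lay closer together. This raised the hypothesis that dasatinib may narrow the spread between tumours. It did not hold for each list. With both treatments the SD was 0.65 in the classically activated list against 0.47 in control, and 0.645 against 0.644 in the chemokine list. The other lists of the 10 had a smaller SD with both treatments than in control. Outside the 10, the SD with both was larger in the monocyte (0.895 against 0.836) and regulatory T cell lists (0.270 against 0.172). It was smaller in the plasma cell (0.392 against 1.09) and dendritic cell lists (0.169 against 0.383). The same held for the complement (0.671 against 1.10) and alternatively activated macrophage lists (0.644 against 1.21). Over 10 immune lists, including the T cell and macrophage lists, the mean absolute deviation from the group median was 0.321 in the libraries with dasatinib and 0.732 in those without, a difference of -0.411 (exact permutation p = 0.0951, two-sided). Without ITC replicate 2 the difference was -0.182 (exact permutation p = 0.229), and over the other 31 lists -0.106 (p = 0.206 by the same exact test). The libraries were too few to tell a smaller spread from chance.

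Xist, which is transcribed from the inactive X chromosome and was chosen after its values were seen, ran from 18.4 CPM in dasatinib replicate 3 to 139 in control replicate 4. Since the hosts were female, a candidate explanation is that Xist follows the share of host stroma. Across the 15 libraries it went with the endothelial level (r = 0.536, permutation p = 0.0364, 0.0729 adjusted over the 2 relations tested, and rho = 0.504, permutation p = 0.0579). Without the 2 farthest libraries r was 0.420, and within groups 0.702. The values go with the explanation, but the relation did not pass after adjustment, and the sex of the injected cells is not stated. None of the 4 genes of the Y chromosome list passed the count filter, and Xist from the injected cells was not excluded.

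The genes called in other divisions of the libraries raised a further hypothesis, a trend with gene length. The division of the control and dasatinib libraries that called the most genes, 399, put control replicates 1 and 2 with dasatinib replicates 3 and 4. The genes lower in these libraries had a median exon length of 7815.5 bp and the higher ones 2350.0 bp, a ratio of 3.33, against 4025 bp for all genes tested. With the slope of expression on length as a covariate, 0 genes were called in edgeR in that division, and the median absolute log2 fold change of the 399 genes went from 0.52 to 0.34 while the median standard error stayed at 0.12. The slope covered 4872 genes (28.0% of those tested), and the coefficient of variation went from 0.226 to 0.186. Control replicate 2, dasatinib replicate 3 and replicate 3 of the combination had the lowest slopes (-0.21, -0.19 and -0.10). They also had the highest shares of counts outside genes classed as protein-coding in GENCODE M21 (5.10%, 3.28% and 3.97%). That share includes identifiers absent from M21, whatever their class. In control replicate 2 and replicate 3 of the combination, the identifier ENSMUSG00000119584.1 alone held 1.64% and 1.10% of counts. The 3 libraries with the lowest slopes also had the highest skeletal muscle levels (5.93, 5.75 and 6.11 in mean log2 CPM). ITC replicate 2, at 5.56, and replicate 1 of the combination, at 5.16, had slopes of 0.01 and 0.05. Muscle in the samples was not tested as a source of the trend. A difference in RNA quality or library preparation may also lie behind it, but the labels record neither.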
